A study of Mus musculus with 8 samples.

How the data were processed

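RNA-seq was measured in 8 mouse malignant mesothelioma samples. The labels place 2 samples in a double knockout group and 6 in a triple knockout group. The study's title and the sample names give the genes concerned as Nf2 and Cdkn2a in the double knockout and Bap1 in addition in the triple knockout. The labels' protocols describe cells kept in culture medium, total RNA, messenger RNA enrichment and a NEBNext Ultra II library kit. Transcripts of leukocytes, endothelium and adult muscle were nevertheless counted in all 8 samples, so it is unclear whether cultures or tissue were sequenced. Replicate numbers were assigned in accession order, so they name samples and pair none. The labels do not say how many mice or cultures the samples came from, so p-values measure the spread between these samples.

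The authors deposited whole-number read counts per gene, one table per sample, with each gene's coordinates. The submitters' processing notes name HTSeq, DESeq2 and the mouse builds mm10 and GRCm38, with no role or order. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. Each table held 52636 genes. Symbols were found for 52403 of them, and 49993 had the coordinates and strand of GENCODE M21 once the starts, which the files count from 0, were moved by 1. Coordinates are printed counted from 1 on GRCm38. Because the use of strand is unknown, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies, such as pseudogenes, carry uncertain counts.

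Total counts per sample ran from 26847202 to 32082535, and 23668 to 24124 genes had at least 1 count. No pair of samples agreed within sampling noise: the lowest median chi-square per gene between 2 samples was 12.7. Intervals from counts and floors cover counting error only. A gene with no count in a group was given a floor of 3 counts over the group, which yields a lower bound of the fold. A gene with 1 to 3 counts in a group has its ratio with an exact binomial 95% interval. Standard errors of fold changes were derived from the test statistic.

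Counts were filtered with filterByExpr, scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) as triple minus double over all 8 samples, with no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 17709 genes tested were called. Levels are counts scaled to library size (CPM) with TMM factors, and log2 levels used a prior count of 2. Gene lists with at least 5 tested members, 28 of them, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Adjusted p-values of camera are over the 28 lists. The deleted genes were also tested with an exact permutation test, 2-sided, over the 28 ways to split 8 samples into 2 and 6, for which the smallest possible p is 0.0357.

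The lists, the tests and the rule for named genes were fixed before the data were examined. The rule takes Bap1, Nf2 and Cdkn2a. It takes the 10 largest log2 fold changes in each direction among called genes with a mean CPM of at least 1 in the higher group, no overlap between the groups, and a symbol of a known gene. From each list it takes up to 4 called members of smallest p, or up to 2 members where none was called. Some genes that the rule takes are not reported here. Other genes named are said to have been chosen after their values were seen. The embryonic myogenic and adult skeletal muscle lists, 20 genes each, were written after the data were examined.

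The tests were checked on counts simulated from these samples' means and library sizes, with 200 of 17419 genes changed. In that simulation edgeR recovered 2% of genes changed 2-fold, 54% at 4-fold, 70% at 8-fold and 92% at 16-fold, with 11 false calls among 120. DESeq2 1.42.0 recovered 22%, 80%, 92% and 98% at these folds, with 95 false calls among 241, and limma-voom 2%, 52%, 66% and 88%, with 8 false calls among 112. With no gene changed, edgeR made 0 calls over 17364 genes, and a list of 30 genes raised 2-fold had a camera p of 3e-19. Each gene was drawn independently, so the simulation holds no correlation between genes and no sample that stands apart. The 5 lists that camera called had estimated correlations of 0.141 to 0.913. The simulation therefore does not show how camera or the false calls of edgeR behave in these samples.

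Alternatives were DESeq2, limma-voom with and without sample weights, RLE and upper-quartile scaling, no filter on low counts, a filter of 1 CPM in at least 2 samples, robust dispersion, the description code in the labels as a term, and leaving out each sample. Genes were filtered anew in each fit without a sample, so list medians there can cover other members than in the main fit. The code SN930 marks 1 double (sample 1) and 3 triple samples (4, 5 and 6). Other codes mark 1 double (sample 2) and 3 triple samples (1, 2 and 3). The labels do not say what the codes mean. A term for the adult muscle score and fits within each set of codes were added after the data were examined. Pseudogene transcripts were compared with coding transcripts of GENCODE M21 by blastn 2.17.0. Lung epithelial markers, of which 2 of 10 passed the filter, and sex-linked genes were not tested as sets.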

Results

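Gene expression was measured by RNA-seq in mouse malignant mesothelioma, a tumour of the lining of the body cavities, with 2 double knockout samples (Nf2 and Cdkn2a) and 6 triple knockout samples (Nf2, Cdkn2a and Bap1). Nf2 encodes the Hippo pathway regulator merlin, Cdkn2a encodes cell cycle inhibitors, and Bap1 encodes a deubiquitinase of histone H2A. Depth was 32082535 and 26847202 counts in double samples 1 and 2, and 28326756 to 30232440 counts in the triple samples. The design holds a single comparison, triple against double, and asks which genes differ when Bap1 is deleted as well, with genes controlled by Polycomb repressive complex 2 (PRC2) of particular interest.

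Transcripts of all 3 targeted genes were counted in every sample, and none differed between the groups by the adjusted test. Bap1 (chromosome 14, 31251450 to 31259944) stood at 106 and 71.2 CPM in the double samples and at 56.8, 60.0, 55.7, 43.1, 72.1 and 63.1 CPM in triple samples 1 to 6, a log2 fold change of -0.60 ± 0.22 (SE; adjusted p = 0.122; exact permutation p = 0.0714). Nf2 (chromosome 11, 4765845 to 4849536) averaged 137 ± 39.6 CPM (SD, n = 2) and 87.9 CPM (n = 6), a log2 fold change of -0.64 ± 0.22 with adjusted p = 0.103 by edgeR and an exact permutation p = 0.0357. Cdkn2a (chromosome 4, 89274471 to 89294653) ranged from 1.54 to 8.76 CPM over the 8 samples, with adjusted p = 0.306. Adjusted over the list alone, 2 of the 3 genes were called, both lower, against 0 over all genes tested. Counts over a whole gene include exons outside the deleted part, so these levels check the labels only weakly. Without double replicate 2 the adjusted p was 0.0349 for Bap1, 0.0254 for Nf2 and 0.0361 for Cdkn2a, whose log2 fold change was then 2.01. That fit holds double sample 1 alone, assumes that it varies like the triple samples, and does not show a difference between the groups.

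Of 17709 genes tested, 520 were higher and 958 lower in the triple samples, 1478 in all. The genes that fell furthest included R3hdml, Dcx (doublecortin, a microtubule-associated protein), Ctrb1 (chymotrypsinogen), Pkp1 (plakophilin 1, a desmosome protein) and Gjd4 (a connexin). R3hdml averaged 123 ± 107 CPM (SD, n = 2) in the double samples and 0.19 ± 0.18 CPM (SD, n = 6) in the triple samples, a log2 fold change of -9.31 ± 0.85. Pkp1 fell by 8.35 ± 0.82, Ctrb1 by 8.56 ± 0.90 and Dcx by 9.10 ± 1.14 on the log2 scale. In double samples 1 and 2 Pkp1 stood at 20.3 and 70.5 CPM, and Ctrb1 at 17.5 and 2.02 CPM. Gjd4, Clrn1, Tekt5, Smim6, Psca and Ighv5-16 had 1 or 2 counts over all 6 triple samples. Gjd4 counts were 703-fold lower there, with a 95% counting interval that began at 193, and the pooled ratios of the other 5 ran from 500 for Clrn1 to 747 for Tekt5. Against double sample 2 alone the ratio was 187 for Gjd4, 200 for Ighv5-16, 120 for Smim6, 113 for Tekt5 and 86.6 for Psca, while that of Clrn1 was 239 against double sample 1 alone. The 95% counting intervals of these ratios began at 13 for Psca to 63.5 for Clrn1. Dcx stood at 96.1 and 3.68 CPM in double samples 1 and 2, and fell by 5.35 without double replicate 1 (adjusted p = 0.0401). Smim6, Tekt5 and Psca lost their call without triple replicate 6, 2 and 3 in turn (adjusted p = 0.0621, 0.0572 and 0.0655).

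Among the genes that rose furthest were the transcription factor Tcfl5, the neuronal pentraxin Nptx2, the imprinted gene Nnat, the adhesion receptor Adgrb3 and AI593442. Tcfl5 rose from 0.19 ± 0.07 CPM (SD, n = 2) to 57.3 ± 30.6 CPM (SD, n = 6), a log2 fold change of 8.19 ± 1.27. Triple sample 3 was far below the other triple samples, at 6.07 CPM. Nptx2 rose by 7.15 ± 1.21 and AI593442 by 7.37 ± 1.43 on the log2 scale. Adgrb3 had 1 count in the double samples and a pooled ratio of 159, with a 95% counting interval that began at 28.4. Csf3 (granulocyte colony-stimulating factor), the natural killer receptor gene Klra1 and the vomeronasal receptor gene Vmn1r53, both from families that vary between mouse strains, had 0 counts in both double samples. Against the floor of 3 counts, Csf3 was at least 32.1-fold higher, Klra1 at least 45.3-fold and Vmn1r53 at least 34.9-fold. Leaving out double replicate 1, Tcfl5, Nptx2, Nnat, AI593442, Adgrb3, Klra1 and Vmn1r53 lost their call, with log2 fold changes from 6.22 for Adgrb3 to 9.30 for Klra1. That fit holds a single double sample, so a lost call is not by itself a smaller difference.

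At an unadjusted p under 0.05 there were 4947 genes, and 24.1% of tested genes showed no overlap between the groups, where chance gives 7.14%. The count of calls rested on individual samples: it was 315 without double replicate 1, 5579 without double replicate 2, and 635 to 930 without any 1 of the triple samples. Of the 60 called genes that the naming rule takes and that are reported here, 32 of 59 tested lost their call without double replicate 1, 9 of 60 without double replicate 2 and 12 to 22 without a triple sample. Double sample 1 stood apart from the other 7. Its log2 levels correlated with those of double sample 2 at r = 0.892 across genes, which are not independent replicates. With the triple samples double sample 1 correlated at 0.804 to 0.878, so double sample 2 was the closest to it. Double sample 2 correlated at 0.903 to 0.93 with each triple sample. Mitochondrial genes took 4.04% of counts in double sample 1 and 1.17% to 2.33% in the others, and its TMM factor was 0.771 against 0.994 to 1.10. Double sample 1 carries the description code SN930 and double sample 2 another code. Fits within a set of codes therefore also differ in the double sample they hold, and the 2 cannot be told apart there. Among samples with the description code SN930 the same test called 2156 genes, among those with other codes it called 1 (2506 at an unadjusted p under 0.05), and with the code as a term it called 962.

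Genes of embryonic muscle were higher in both double samples. In a list of 20 embryonic myogenic genes, written after the data were examined, 19 fell and 0 rose in the triple samples, with a median log2 fold change of -6.23. The muscle-determining factor Myog stood at 510 and 377 CPM in the double samples and at 0.199 to 17.8 CPM in the triple samples. Myod1, another such factor, stood at 95.9 and 128 CPM against 2.99 ± 3.41 CPM (SD, n = 6), embryonic myosin Myh3 at 2450 and 636 CPM against at most 18.8 CPM, and Cdh15 (M-cadherin) at 333 and 343 CPM against at most 4.65 CPM. Genes of adult skeletal muscle did not part the groups: 0 of 20 were called, with a median log2 fold change of -2.43. The adult list took 3.68% of all counts in double sample 1 and 0.244% in double sample 2, against 1.48% in triple sample 2 and 0.0129% to 0.608% in the other triple samples. Among the 11 muscle markers fixed beforehand, 1 fell (Actg2, smooth muscle actin, by 3.49 ± 0.61) and 10 did not pass the test (camera adjusted p = 0.162; 1 called when adjusted over the list alone). The median of these markers was -1.84, and 1.14 without double replicate 1. Without double replicate 1, 8 of the 20 embryonic genes were called lower, and without double replicate 2 all 20 were. Actg2 stood at 9.47 and 44.8 CPM in double samples 1 and 2, and gave -1.96 without double replicate 2 (adjusted p = 0.0548).

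**Figure D1:**
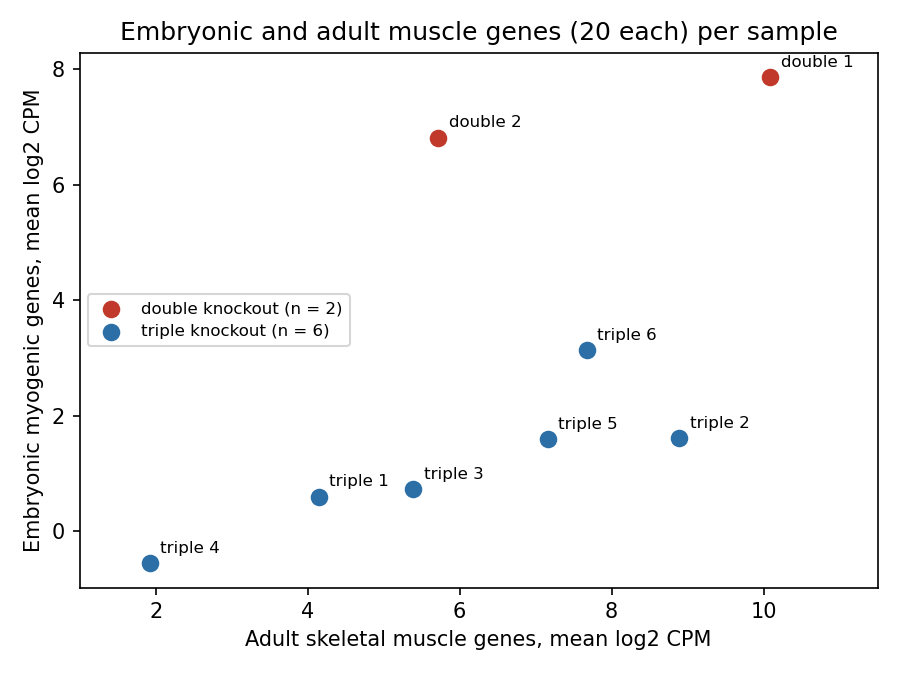
Mean log2 CPM of 20 embryonic myogenic genes (vertical axis) against that of 20 adult skeletal muscle genes (horizontal axis), 1 point per sample, double knockout in red and triple knockout in blue. The double samples stand at 7.86 and 6.81 on the embryonic axis and the triple samples between -0.56 and 3.13, while double sample 2 lies at 5.72 on the adult axis, among the triple samples.

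Developmental transcription factor genes known as PRC2 targets moved in both directions. Of 75 tested members outside the Hox clusters, 4 rose, 11 fell and 60 did not pass the test (6 higher and 14 lower when adjusted over the list alone). Those that rose included Lhx6, Foxf1 and Gli2, a Hedgehog effector (the last 2 named after their values were seen). Lhx6 rose from 1.98 to 20.2 ± 7.51 CPM (SD, n = 6), a log2 fold change of 3.34 ± 0.45. Dlx3 fell from 6.08 ± 3.96 to 0.04 ± 0.03 CPM, 140-fold lower, Sox8 fell by 4.63 ± 0.68, and Pax3, a factor of muscle precursors, fell by 4.60 ± 0.53. Pax7, which also acts in muscle precursors, fell too (chosen after its values were seen). The list as a whole showed no shift to one side relative to other genes, with a median log2 fold change of -0.17. Its camera adjusted p was 0.30, and 0.801 with an estimated correlation. Camera tests only such a shift. Called members numbered 15 of 75, against 1478 of 17709 over all genes tested. Fry's test for changes in either direction, which makes no comparison with other genes, gave adjusted p = 8.92e-08 over the 28 lists. The same test was under 0.05 for many other lists, such as the epithelial (2.23e-06), imprinted (1.22e-05) and calcium release and ferroptosis genes (0.0223). For others, such as the interferon list (0.337), it was not. A value under 0.05 was therefore not particular to these targets. Without double replicate 1 the list median was 0.40, and without double replicate 2 it was 0.20. Genes were filtered anew in those fits, with 18638 and 18893 tested, so these medians can cover other members.

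In the Hox clusters, which set position along the body axis, 3 of 24 tested genes fell, 0 rose and 21 did not pass the test (4 lower when adjusted over the list alone). All 3 lie side by side in the HoxA cluster on chromosome 6. Hoxa7 fell from 29.9 ± 0.69 CPM (SD, n = 2) to 0.96 ± 0.62 CPM (SD, n = 6), by 4.95 ± 0.54 on the log2 scale, Hoxa6 fell by 4.08 ± 0.51, and Hoxa9 fell by 7.20 ± 1.07. Hoxa9 was at -3.94 without double replicate 2 (adjusted p = 0.0233). The median of the cluster genes was -0.35 and the camera adjusted p = 0.115. It was 0.0392 without triple replicate 5 and 0.0280 with sample weights, over a range of 0.028 to 0.801 in all alternatives.

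The PRC2 subunits themselves gave no call: 0 of 12 were called, with values of 1.22 ± 0.41 for Epop (adjusted p = 0.103) and -0.77 ± 0.26 for Ezh1 (adjusted p = 0.104) on the log2 scale, and camera adjusted p = 0.824. Ezh1 stood at 95.2 and 46.0 CPM in double samples 1 and 2, and was at -1.19 without double replicate 2. Of 20 PRC1 subunits, 2 fell and 18 did not pass: Cbx7, a chromodomain reader of H3K27 methylation, by 1.88 ± 0.35 and Pcgf5 by 0.90 ± 0.20 (2 higher and 3 lower when adjusted over the list alone; camera adjusted p = 0.824). Pcgf5 lost its call without triple replicate 1, 4, 5 or 6 (adjusted p = 0.0515 to 0.0638). Both lost their call without double replicate 1, where Cbx7 was at -1.32 and Pcgf5 at -0.91. None of 12 Bap1 partner genes was called, with Asxl3 at 2.28 ± 0.87 and Foxk2 at 0.37 ± 0.20 (camera adjusted p = 0.824). Asxl3 stood at 0.12 and 1.34 CPM in double samples 1 and 2, and was at 4.85 without double replicate 2. None of 21 protocadherin beta genes was called (median -0.30, camera adjusted p = 0.323), among them Pcdhb22 at 0.92 ± 0.47 and Pcdhb16 at -0.56 ± 0.36. The median was -0.11 without double replicate 1, -0.13 without double replicate 2 and -0.49 without triple replicate 5. The counts adjusted over the list alone were 0 for the PRC2 subunits, the partner genes and the protocadherins. Among 13 Wnt ligands Wnt9a fell by 1.40 ± 0.23 and 12 did not pass (1 when adjusted over the list alone; camera adjusted p = 0.763).

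Imprinted genes, which are expressed from the allele of a single parent, moved in both directions. Of 23 tested, 5 rose, 4 fell and 14 did not pass the test, with the same counts when adjusted over the list alone. Meg3 (chromosome 12, 109541001 to 109571726) and Rian, non-coding RNAs of the Dlk1 locus, rose by 3.96 ± 0.38 and 4.37 ± 0.38 on the log2 scale, Rian from 36.5 ± 10.4 CPM (SD, n = 2) to 753 ± 172 CPM (SD, n = 6), and Dlk1, Ndn and Nnat rose as well. Of the imprinted genes named here, Dlk1, Ndn, Zim1, Usp29 and Igf2 were chosen after their values were seen. Peg3 (chromosome 7, 6703892 to 6730431), a zinc finger gene, fell by 5.50 ± 0.48, from 416 ± 199 to 9.18 CPM, and its neighbours Zim1 and Usp29 fell with it. H19, a fetal growth regulator RNA, fell from 6766 to 448 CPM, by 3.92 ± 0.46, and its neighbour Igf2 stood at 4104 and 1841 CPM against 16.6 to 1290 CPM with adjusted p = 0.159. The list did not move one way (median 0.21, camera adjusted p = 0.663). Its median was 0.55 without double replicate 1, 0.50 without double replicate 2 and 0 without triple replicate 5. Nnat lost its call without double replicate 1 (at 7.26) and without double replicate 2 (at 6.65).

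**Figure D2:**
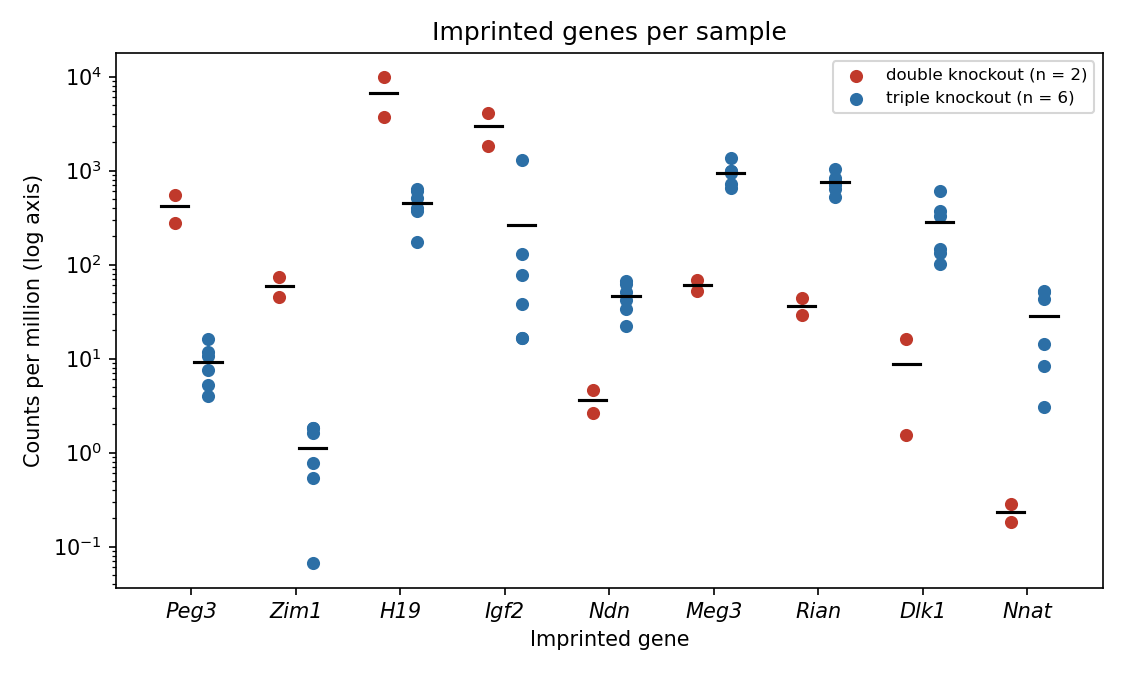
CPM (log axis) of 9 imprinted genes in each of the 2 double (red) and 6 triple (blue) knockout samples; black bars are group means. Peg3 averages 416 CPM in the double and 9.18 CPM in the triple samples, and Meg3 averages 60.4 and 937 CPM.

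Of 26 proliferation and E2F genes, which act in the cell cycle, 25 had a positive log2 fold change, with a median of 0.78, and 1, E2f1, was called, up by 1.36 ± 0.34 (0 called when adjusted over the list alone). The camera test gave adjusted p = 6.32e-05, but adjusted p = 0.801 with an estimated correlation and 0.227 with fry. The mean log2 CPM of the list was 4.10 in double sample 1 and 5.86 in double sample 2, which lay among the triple samples at 5.64 to 6.13. Without double replicate 1 the list had a median of 0.11 and adjusted p = 0.591, and E2f1 was at 0.83 with adjusted p = 0.12. Without any 1 of the triple samples E2f1 had adjusted p of 0.0699 to 0.0855. With the adult muscle score as a term the list had a median of 0.69 and adjusted p = 0.00108. Among 20 homologous recombination genes none was called (median 0.38; camera adjusted p = 0.106; 0 when adjusted over the list alone), and adjusted p = 0.801 with an estimated correlation. The list had a median of 1.16 and adjusted p = 0.000165 without double replicate 2, but -0.07 and adjusted p = 0.796 without double replicate 1. Its mean log2 CPM was 2.60 in double sample 1, 4.05 in double sample 2 and 3.74 to 4.01 in the triple samples.

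Of 19 cholesterol synthesis genes 3 rose, 0 fell and 16 did not pass (4 higher when adjusted over the list alone), with a median log2 fold change of 0.73. The camera adjusted p was 0.00213, but adjusted p = 0.801 with an estimated correlation and 0.129 with fry. Sc5d, a late enzyme of the pathway, rose by 0.93 ± 0.21 on the log2 scale, from 25.4 ± 3.37 CPM (SD, n = 2) to 48.4 ± 7.54 CPM (SD, n = 6). It lost its call without double replicate 1 (adjusted p = 0.224) and without triple replicate 1, 2, 3, 4 or 6 (0.0623 to 0.0675). Of 40 collagen and matrix genes, 4 rose, 3 fell and 33 did not pass (13 higher and 5 lower when adjusted over the list alone). Fbln5 rose by 2.27 ± 0.45 and the basement membrane gene Nid1 by 1.56 ± 0.31, while Lama5, a laminin chain, fell by 2.21 ± 0.37 and Nid2 by 1.58 ± 0.26. The list had a median of 0.77 and camera adjusted p = 0.0124, but adjusted p = 0.801 with an estimated correlation, 0.129 with fry and 0.0514 without double replicate 2. Fbln5, Nid1 and Lama5 lost their call without double replicate 1. Their log2 fold changes were then 2.54, 1.75 and -2.42, each further from 0 than over all 8 samples.

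Markers of other cell types were compared in the same way. Among 18 leukocyte markers Cd68, a macrophage protein, rose by 1.26 ± 0.27 and Itgam by 1.89 ± 0.46, 16 did not pass (3 higher when adjusted over the list alone), and camera gave adjusted p = 0.0204, or adjusted p = 0.801 with an estimated correlation and 0.238 with fry. The list had a median of 0.07 and camera adjusted p = 0.836 without double replicate 1, the sample with 4.04% mitochondrial counts and the most adult muscle transcripts. Cd68 then had adjusted p = 0.187, and Itgam was at 1.25 with adjusted p = 0.134. Without any 1 of the triple samples Itgam had adjusted p of 0.0668 to 0.0758, and Cd68 lost its call without triple replicate 1, 2, 4 or 6 (0.0506 to 0.057). With the adult muscle score as a term the list had adjusted p = 0.0697. Transcripts of leukocytes were present in all 8 samples, with Csf1r, the macrophage growth factor receptor (chosen after its values were seen), at 126 and 290 CPM in the double samples and 389 to 574 CPM in the triple samples. The labels describe cultured cells, while transcripts of leukocytes, endothelium and adult muscle were counted in all 8 samples. It is therefore unclear whether cultures or tissue were sequenced, and marker levels can follow the mix of cells as well as levels within them. Of 28 interferon response genes none was called, with Irf9 at 0.80 ± 0.46 and Gbp2 at 1.79 ± 0.90 (0 when adjusted over the list alone). Irf9 stood at 15.7 and 52.6 CPM in double samples 1 and 2, and was at 1.93 without double replicate 2. In the interferon list 26 genes had a positive log2 fold change. Camera gave adjusted p = 0.0188 for it, or adjusted p = 0.801 with an estimated correlation and 0.419 with fry. The camera direction of that list was down without double replicate 1, with a median of 0.02 and adjusted p = 0.796. The list also lost its call without triple replicate 5 (median 0.39; adjusted p = 0.0573), with DESeq2 (0.0734) and with the adult muscle score as a term (0.118). Among 14 genes of MHC class I presentation none was called (median 0.62; camera adjusted p = 0.107; 0 over the list alone), with Tapbp at 0.78 ± 0.36 and Psmb8 at 1.32 ± 0.64. That list had adjusted p = 0.0171 without triple replicate 3, but 0.836 without double replicate 1 (median 0.26), and adjusted p = 0.801 with an estimated correlation.

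Of 13 fibroblast markers Pdgfra rose by 1.83 ± 0.41 and Cd34 by 1.70 ± 0.43, and 11 did not pass (2 when adjusted over the list alone; camera adjusted p = 0.156). Of 12 endothelial markers Tek fell by 1.83 ± 0.48 and 11 did not pass (0 when adjusted over the list alone; adjusted p = 0.892). Tek stood at 89.7 CPM in double sample 1 and at 20.8 CPM in double sample 2, and gave -0.43 without double replicate 1 (adjusted p = 0.747). It lies on chromosome 4 (94739289 to 94874976), in a block from 94 to 100 Mb whose genes were raised in double sample 1. Of 22 mesenchymal genes Twist2 rose by 3.69 ± 0.68 and Postn (periostin) by 1.58 ± 0.41, and 20 did not pass (4 higher and 1 lower when adjusted over the list alone; adjusted p = 0.0603). The mesenchymal list had adjusted p = 0.0245 without triple replicate 3 and 0.0392 without triple replicate 5, but 0.299 without double replicate 1, 0.154 with fry, and adjusted p = 0.801 with an estimated correlation. Of 15 epithelial genes Epcam and Cldn1 rose by 2.90 ± 0.67 and 2.86 ± 0.66, Lamb3 and Pkp2 fell by 4.88 ± 0.39 and 2.70 ± 0.62, and 11 did not pass (4 higher and 4 lower when adjusted over the list alone; adjusted p = 0.824, with a positive median and a negative direction by camera). Among 18 mesothelial markers Aldh1a2, a retinoic acid enzyme, rose by 4.34 ± 1.11 and 17 did not pass (0 when adjusted over the list alone; median 2.41; adjusted p = 0.323). The list median was 0.47 without triple replicate 3, and 4.16 without double replicate 1, over the members that passed the filter in each fit. Cd34 and Tek lost their call without any 1 of the triple samples. Pdgfra, Postn, Epcam, Cldn1, Pkp2 and Aldh1a2 lost theirs without some of these samples, while Twist2 and Lamb3 did not. Each gene said here to have risen or fallen, except Lamb3, lost its call without double replicate 1. There the log2 fold changes were 2.05 for Pdgfra, 1.24 for Cd34, 3.68 for Twist2, 1.55 for Postn and -0.43 for Tek. Epcam was at 2.52, Cldn1 at 2.38, Pkp2 at -2.93 and Aldh1a2 at 4.56. Of 10 lung epithelial markers 2 passed the filter, with Napsa at 9.31 and 8.96 CPM and Ager at 3.61 and 3.18 CPM in the double and triple groups, and 0 of 2 called (0 when adjusted over the list alone).

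In stress and signalling lists few members were called. Of 19 p53 target genes Pmaip1 and Perp, both linked to apoptosis, fell by 2.95 ± 0.38 and 4.16 ± 0.81, and 17 did not pass (1 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.162). Perp stood at 66.8 CPM in double sample 1 and at 3.65 CPM in double sample 2, within the triple range, and gave -0.89 without double replicate 1 (adjusted p = 0.651). The median of the p53 targets was -0.41, and 0.24 without double replicate 1. Of 22 YAP/TAZ target genes Fjx1 rose by 1.92 ± 0.48, Gadd45a and Ankrd1 fell by 3.71 ± 0.67 and 2.63 ± 0.67, and 19 did not pass (1 higher and 4 lower when adjusted over the list alone; adjusted p = 0.896, with median and mean of opposite sign, 0.22 and -0.16). Gadd45a stood at 356 and 70.1 CPM in double samples 1 and 2, and was at -2.11 without double replicate 1 (adjusted p = 0.219). Fjx1 and Ankrd1 then had adjusted p = 0.0997 and 0.28. Of 14 stem cell-associated genes Nes (nestin) fell from 897 ± 98.3 to 95.9 ± 64.1 CPM, and Sox2 and Abcg2 fell by 3.26 ± 0.76 and 1.12 ± 0.27, while 11 did not pass (3 when adjusted over the list alone; adjusted p = 0.507). Sox2 stood at 14.7 CPM in double sample 2 and 0.85 CPM in double sample 1, and gave adjusted p = 0.951 without double replicate 2, while Nes and Abcg2 gave 0.0774 and 0.166 without double replicate 1. Of 19 ATF4 and ER stress genes the amino acid transporter gene Slc7a5 fell by 1.45 ± 0.31. The other 18 did not pass (1 called when adjusted over the list alone, camera adjusted p = 0.162). Slc7a5 lost its call without double replicate 1, where it was at -1.18. Sox2 lost its call without any 1 of the triple samples, and Slc7a5, Abcg2, Fjx1 and Ankrd1 without most of them. Of 22 cytokine genes Csf3 was called and 21 were not (3 higher when adjusted over the list alone; adjusted p = 0.0603). The cytokine list had adjusted p = 0.0245 without triple replicate 3 and 0.0422 without triple replicate 5, but 0.475 without double replicate 1 and adjusted p = 0.801 with an estimated correlation. None of 14 calcium release and ferroptosis genes was called (1 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.892), with Aifm2 at -1.81 ± 0.51 and Itpr3 at 1.03 ± 0.30. Aifm2 stood at 85.5 and 15.6 CPM in double samples 1 and 2, and Itpr3 at 31.3 and 61.7 CPM. Without double replicate 2 they were at -2.55 and 1.61. None of 16 glycolysis genes was called (0 when adjusted over the list alone, camera adjusted p = 0.106). Pfkm was at -2.76 ± 0.85 and Hk2 at -1.65 ± 0.60, both positive without double replicate 1. The glycolysis list had adjusted p = 0.0285 without triple replicate 6, but 0.836 without double replicate 1 (median -0.02), and adjusted p = 0.801 with an estimated correlation. In the lists with 0 calls by edgeR, the members at an unadjusted p under 0.05 numbered 4 for glycolysis, 4 for calcium release and ferroptosis, 3 for adult skeletal muscle, 2 for the PRC2 subunits, 1 for the Bap1 partners, 1 for homologous recombination, 2 for the targeted genes and 0 for the interferon, MHC, protocadherin, lung epithelial and sex-linked genes. DESeq2 called 3 calcium release and ferroptosis genes, 2 adult muscle genes and 1 each among the PRC2 subunits, Bap1 partners and glycolysis genes, and limma-voom called 0 in all of these lists.

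**Figure D3:**
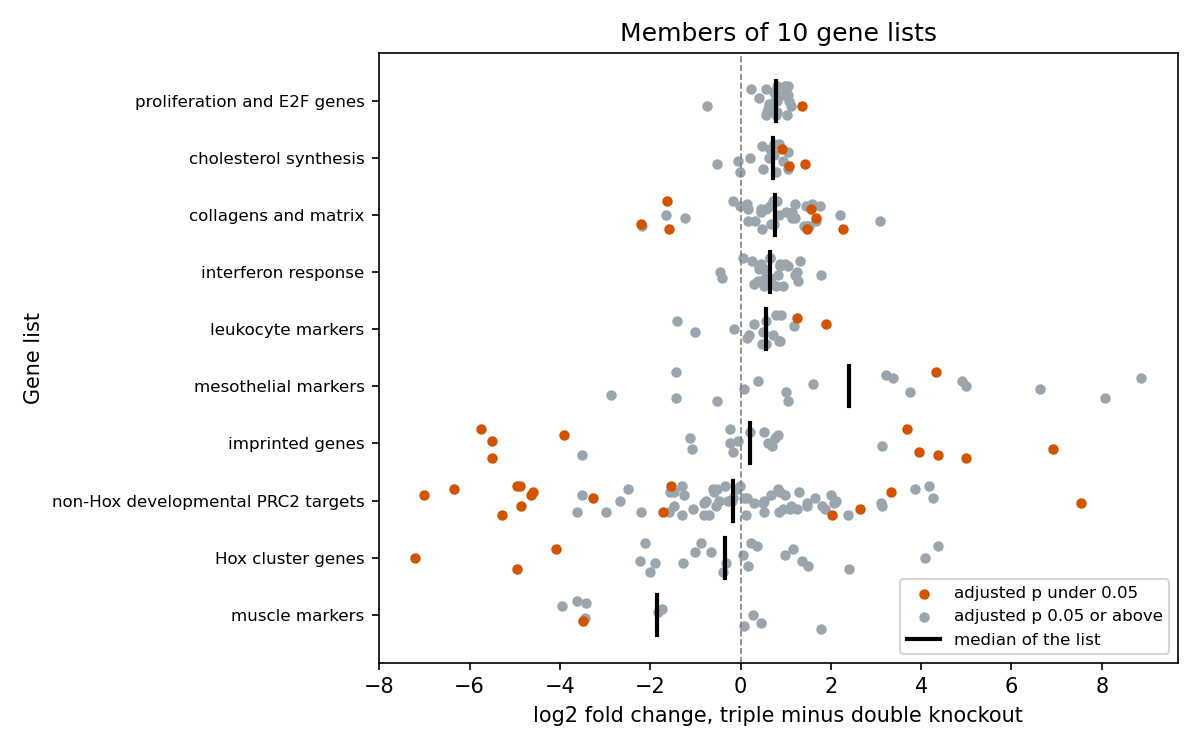
Log2 fold change (triple minus double knockout) of each tested member of 10 gene lists, 1 point per gene, orange where the edgeR adjusted p was under 0.05 and grey otherwise; black bars are list medians and points are spread vertically for legibility. Proliferation genes cluster around a median of 0.78 with 1 member called, while imprinted genes and developmental PRC2 targets have called members on both sides of 0.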

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

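The tests of adult muscle on the embryonic genes, of tumour type, of read handling, of strain, of a few strong genes and of a chromosome gain were chosen after the results were seen, while those of near-identical coding genes, of muscle on chromosome 8 and of other splits of the samples were written down beforehand.

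In 13 of 113 values tested, 1 triple sample lay far from the other 5, by a gap to its nearest neighbour that took most of the group's range; chance gives such a gap in about 1 of 20 groups. In 5 of these the gene had counts in a single triple sample, which fixes the gap at 1. Of the other 108 values 8 had such a gap (7.41%), close to what chance gives. Triple sample 3 was lowest for Tcfl5 (6.07 CPM; gap 0.725 of the range) and total counts (0.637), and highest for Psca (1) and for the mesothelial marker score (0.717). Triple sample 5 was highest for Cldn1 (0.675), Tapbp (0.686), Clrn1 (1) and Ighv5-16 (1), and triple sample 6 for Gadd45a (0.745) and Smim6 (1). Triple sample 2 was highest for Tekt5 (1), triple sample 1 lowest for Cbx7 (0.776) and triple sample 4 lowest for Nf2 (0.7).

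The embryonic muscle programme in both double samples was weighed against adult muscle tissue in the samples. With the adult muscle score as a term the median log2 fold change of the adult genes went to -0.13. Of the 20 embryonic genes, 19 were called lower in the triple samples (18 of them also called without the term). Their median moved from -6.23 to -5.41. The list was written from genes seen to be high in both double samples, so these values are not independent support against adult muscle. The median log2 difference of double sample 2 minus each of the 6 triple samples was 3.55 to 8.18 for the embryonic genes and -3.53 to 3.96 for the adult genes, below 0 against 4 of them. Both double samples lay above all 6 triple samples for all 20 embryonic genes, but the list was written from this pattern, so that count decides nothing, and a muscle-like tumour type such as rhabdomyosarcoma, which expresses these genes, cannot be told apart from the genotype with 2 double samples. Regenerating muscle in the double samples was not tested and stays open.

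Some pseudogenes were on in one genotype and off in the other. Of 934 tested, 25 called pseudogenes on 11 chromosomes were at 5% or less of the other group's mean in every sample of a group. In 24 of them the double samples were off. The rule was not applied to coding genes, so the pattern is not shown to be particular to pseudogenes. Of tested pseudogenes 4.82% were called higher and 1.39% lower in the triple samples, against 2.91% and 5.82% of coding genes. Gm10704 stood at 0.445 and 0.542 CPM in the double samples and 18.7 to 24.1 CPM in the triple samples. A different handling of reads that match several places was taken to move most pseudogenes with a near-identical coding transcript, at 95% identity or more. Of 682 such pseudogenes 5.13% differed by 8-fold or more. The premise was not tested, and at that identity many reads can still match a single place, so the percentage does not decide. This test replaced a comparison of medians over all pseudogenes (0.048) and coding genes (0.009), which decides nothing because members moved both ways. Near-identical coding transcripts were less frequent among called pseudogenes of at least 8-fold than among those not called (53.7% of 41 against 73.9% of 876, difference -20.2 points, Fisher's exact p = 0.00661). For the 41 as a set, that argues against reads shared with coding genes as the whole cause. Shared reads stay open for the 22 of them with such a transcript. The 25 on and off genes were not tested apart. A strain difference between the mice could give the 25 on and off genes, and Klra1 and Vmn1r53, from families that vary between strains, were at 0 in the same samples, but strain cannot be told apart from genotype here.

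Genes of chromosome 8 were higher in both double samples: 126 of 930 tested fell in the triple samples and 11 rose, 13.5% called lower against 4.96% elsewhere. The sample medians gave an exact permutation p of 0.0357, the smallest possible, and adjusted p = 0.102 over 20 chromosomes. Chromosomes 1, 2, 4, 7, 17 and 19 had the same values, and 9.52% of chromosome 19 genes were called lower. The median gene of chromosome 8 lay 0.29 and 0.33 log2 units above the triple median in double samples 1 and 2. On the other chromosomes it lay at -0.25 to 0.13 and -0.08 to 0.37. With the adult muscle score as a term chromosome 8 stayed at -0.32 relative to all genes, which argues against adult muscle tissue. Embryonic muscle was not tested. Medians and shares of negative fold changes here cover genes with a mean CPM of at least 5, of which chromosome 8 held 640. Negative fold changes were 20.4 points more frequent on it than elsewhere. That argues against a few strong genes, but it is not independent of the raised median. In 12 of 13 bins of 10 Mb the median was above 0 in both double samples, but so it was in 6 of 7 bins of chromosome 19, where the median of double sample 1 was 0.03, so the bins do not decide. A gain of the whole chromosome stays open, because DNA was not analysed here.

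Chance in how the samples fell into groups was weighed against the other splits. The real split called 1478 genes, and the highest of the other splits called 3. Only 1 of the 28 splits, the real one, called as many, a share of 0.0357 and the smallest that 28 splits allow. That share argues against chance as the source of the calls but cannot exclude it. Every other split leaves a double sample in the larger group, which can widen the spread there. The comparison of splits says nothing on whether the genotype or another difference between the groups gave the calls. Double sample 1 stood apart from the other 7, and 315 genes were called without it.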

How the results depend on the processing

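Among alternatives chosen before the data were examined, DESeq2 called 3380 genes (1498 higher, 1882 lower), sample weights 99 (7 and 92) and the description code as a term 962 (593 lower); leaving out each sample gave 315 to 5579 calls, 103 to 2592 higher and 212 to 2987 lower. Of the 1478 calls, 1462, 99 and 919 were kept under these 3 settings in turn, 252 without double replicate 1, 1334 without double replicate 2 and 628 to 886 without a triple sample; the other scalings, filters, limma-voom and robust dispersion gave 1070 to 1548. Sample weights put 0.343 and 0.350 on the double samples, and DESeq2 made more true and more false calls in simulation, which does not tell which its added calls are; for the other settings the cause was not tested beyond the loss of samples. Of alternatives added after the data were seen, the adult muscle score as a term gave 842 calls (328 higher, 514 lower), the SN930 samples alone 2156 (887 higher) and the other codes alone 1 (0 higher, 1 lower), where a lone double sample is assumed to vary like the triple samples. The lone double sample was double sample 1 for SN930 and double sample 2 for the other codes, so code and double sample cannot be told apart there. The median of the Hox genes was -0.66 with sample weights and -0.71 to 0.08 when samples were left out. Developmental PRC2 targets were called as a list shifted to one side under none of 19 alternatives. With the code as a term, the 5 list calls had adjusted p-values of 0.000149 to 0.0276, and none held with an estimated correlation. Without double replicate 1 the direction by camera turned for the interferon list, whose median stayed above 0 (0.02, and 2.17 without double replicate 2), and the sign turned for Pfkm (0.22, and -3.65), Hk2 (0.19, and -2.42) and Ager (0.50, and -0.63), as it did for Napsa without double replicate 2 (0.40, and -0.40 without double replicate 1) and without triple replicate 3 (0.05); of these only the interferon list had been called, and the cause was not tested. The direction by camera also turned without double replicate 1 for 7 lists that were called in neither fit: the p53 targets (median 0.24), muscle markers (1.14), homologous recombination, YAP/TAZ target, epithelial, endothelial, and calcium release and ferroptosis lists. Among called genes, 27 of 1477 tested had the opposite sign without double replicate 1, 1 of 1475 without double replicate 2, 2 of 1472 in the SN930 samples alone and 28 of 1468 in the other codes alone. Of the 60 called genes that the naming rule takes and that are reported here, 32 of 59 tested lost their call without double replicate 1, 9 without double replicate 2, 12 to 22 without a triple sample, 41 with sample weights, 16 with limma-voom, 16 with the adult muscle score as a term and 14 with the code as a term. In simulation edgeR recovered 2% of genes changed 2-fold and DESeq2 22%; neither the number of samples nor the depth was varied.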

Other observations

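The following values were picked after the data were examined. Mesothelial keratin and uroplakin genes were prominent in triple sample 3: Upk3b stood at 173 CPM there and at 0.365 CPM or less in the other 7 samples, Krt19 at 52.9 CPM against at most 0.734 CPM, and Wt1, a mesothelial transcription factor, at 33.2 CPM against at most 1.76 CPM. Msln (mesothelin) did not follow them, with 251 and 342 CPM in the double samples and 12.6 to 194 CPM in the triple samples. The same sample had Xist at 344 CPM and the Y-linked gene Ddx3y at 1.73 CPM, while the other 7 samples had Xist at 10.0 CPM or less and Ddx3y at 27.4 to 139 CPM.

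Double sample 1 had a block of raised genes on chromosome 4 between 94 and 100 Mb. The 24 expressed genes there had a median log2 level 1.64 above the triple samples, against 0.27 in double sample 2, and 15 of them were more than 1 above. Jun, the AP-1 transcription factor, stood at 544 CPM in that sample, 106 CPM in double sample 2 and 151 to 202 CPM in the triple samples, and Patj at 351 CPM against 2.32 to 15.4 CPM in the other 7 samples. Outside the block on the same chromosome, Mtap stood at 39.9 CPM in double sample 1, 146 CPM in double sample 2 and 183 to 365 CPM in the triple samples. It lies close to the targeted gene Cdkn2a, which stood at 1.54, 5.16 and 4.05 to 8.76 CPM in the same order. Cdkn2b, also close by, stood at 20.7, 67.9 and 46.4 to 102 CPM. Genes of chromosome 19 had a median log2 level 0.37 above the triple samples in double sample 2 and 0.03 above them in double sample 1.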
